A study of Homo sapiens with 9 samples.

How the data were processed

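RNA of MDA-MB231 cells was hybridised to Illumina bead arrays, with 3 arrays for each of vector, RAI2 and RAI2-4A. Per the labels' protocols, cells were transduced with retrovirus made in packaging cells, selected with 2 µg/ml puromycin and kept under selection for 4 days, and biotin-labelled cRNA was made from 500 ng of total RNA. The submitters' processing notes name BeadStudio and limma, with no version given. The deposited value table holds intensity values on a linear scale for 47323 probes. The deposited intensities had medians of 98.5 to 99.5 on all arrays, so they were taken as already normalized between arrays, by a method not given in the sources used here. A further 18 columns (9 signals and 9 detection p columns) bear names that match no single sample's labels, and were not used here. The plan had been to normalize raw signals with neqc and to filter on detection p. Both were replaced by normexp on the deposited intensities and by a background threshold taken from them. With 1 value per probe and array, the number of arrays limits precision.

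The 3 probes with a missing value were left out. The median of the background estimate was an intensity of 73.2. Background was corrected per array with limma's normexp model (saddle-point fit, offset 50) and log2 was taken, with no further normalization. A probe counted as above background on an array when its log2 intensity exceeded the mode of that array's distribution by 1.645 SD, the SD being taken from the side below the mode (density bandwidth 0.03). The thresholds were intensities of 99.9 to 104, and 42.5% to 47.8% of probes lay above. Probes above background on at least 3 of 9 arrays were kept, 22344 in all. The probe table names 1 gene symbol for 30111 probes, and several or none for the rest. Through the Entrez IDs, 30074 were found in the RefSeq gene table of GRCh38.p14, which changed 0 symbols. That table was used only for names and for which genes neighbour each other. Each gene was represented by its brightest kept probe, giving 12420 genes.

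A linear model over all 9 arrays with 6 residual degrees of freedom was fitted with lmFit, contrasts.fit and eBayes of limma 3.58.1 in R 4.3.3, with 3 two-sided contrasts. P-values were adjusted by Benjamini-Hochberg over the genes of each contrast, at a threshold of 0.05. Where none of a gene's probes was above background on any array of a group, a lower bound on the fold is given. Gene lists, 39 in number and holding 931 genes, were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a contrast. The comparisons, lists, alternatives and rule for named genes were fixed before the data were examined. That rule took RAI2, then, among genes past the threshold, above background on all 3 arrays of at least 1 group and without overlap between groups, the 10 largest rises and 10 largest falls, and up to 4 members past the threshold per list. Of lists without such a member, the 2 brightest members were to be named. They are left out here, and members passing over their list alone are named instead. Those members, CDH1 and the genes named under other observations were chosen after their values were seen. The adjustment over a list alone was made separately for each list and contrast, with no correction across them.

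The fit was tested on simulated data for 12420 genes with the real means and spreads and noise drawn independently per gene. For RAI2 against vector it recovered 44.2% of genes changed by 0.5 log2 units, 91.8% of those changed by 1 and 99.1% of those changed by 2, and 3.85% of calls were false. In other simulated data, which carried the main axis of the residuals, 5.67% of calls were false with that axis as a covariate. These rates come from different simulated data and cannot be compared. The first does not cover noise shared between genes, as on that axis. Alternatives covered background correction, normalization, filter, probe rule, variance model, array weights, replicate block and each array left out in turn. Of the planned ones that named raw signals, normexp on raw values was not run, and those without background correction, with arrays scaled to 1 median and with cyclic loess were run on the deposited values instead. The stricter filter, planned on detection p, required 2.326 SD above the mode on all 9 arrays. The slide as a block was not run, because no slide is given in the sources used here. Added after seeing the data were quantile normalization after background correction, a normexp fit with the background at each array's mode (offset 16), the 3 arrays left out together, the residual axis as covariate, and a replicate block over RAI2 and RAI2-4A only. Same-numbered RAI2 and RAI2-4A arrays deviated together from their group means, with residual correlations of 0.445, 0.437 and 0.231. The numbers may therefore pair these groups, as read from the data and not from the labels. Some arrays with different numbers were correlated as strongly, as vector replicate 1 was with RAI2-4A replicate 2 (0.538) and RAI2 replicate 2 (0.483). A simulation of unchanged groups was run with the same-number correlation too, but without those of vector replicate 1. The possible pairing was noticed after the fit with a block over all groups had been seen. No pair of arrays was identical.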

Results

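Transcript levels were measured on single-colour Illumina bead arrays in MDA-MB231, an established human breast cancer line, after retroviral transduction and puromycin selection. There were 9 arrays in 3 groups of 3: cells that received the empty vector, cells that overexpressed RAI2 (retinoic acid induced 2, a protein reported to bind the CtBP corepressors), and cells that overexpressed a form named RAI2-4A. The labels do not say what 4A denotes, and it is not interpreted here. The labels also do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples. Between 20099 and 22626 probes per array lay above background, and the number of arrays limits the precision of each value. After filtering, 12420 genes were tested. The comparisons asked how RAI2 and RAI2-4A changed the transcriptome relative to vector, and how they differed from each other. Pearson's r between log2 intensities, across probes, which are not independent replicates, ranged from 0.971 to 0.994 over pairs of arrays. Vector replicate 1, RAI2 replicate 2 and RAI2-4A replicate 2 shared a deviation from their own groups, and each count of genes is therefore also given without these 3 arrays, a choice made after seeing the data.

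The RAI2 transcript followed the labels in all 9 arrays. Its only probe (ILMN_1760574) was not above background in any vector array, at a deposited intensity of 90.1 ± 4.97 (SD, n = 3), and read 598 ± 36.8 (SD, n = 3) in RAI2 cells and 1059 ± 101 (SD, n = 3) in RAI2-4A cells. RAI2 was at least 7.21-fold higher than vector in RAI2 cells (limma, adjusted p = 5.75e-09) and at least 13-fold higher in RAI2-4A cells (limma, adjusted p = 2.51e-10). Both bounds set the group's mean of log2 values against the higher, per vector array, of the lowest value among probes above background and the probe's own value. The RAI2-4A arrays read higher than the RAI2 arrays, with a log2 difference of -0.85 (SE 0.11) for RAI2 minus RAI2-4A (limma, adjusted p = 0.00279).

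**Figure D1:**
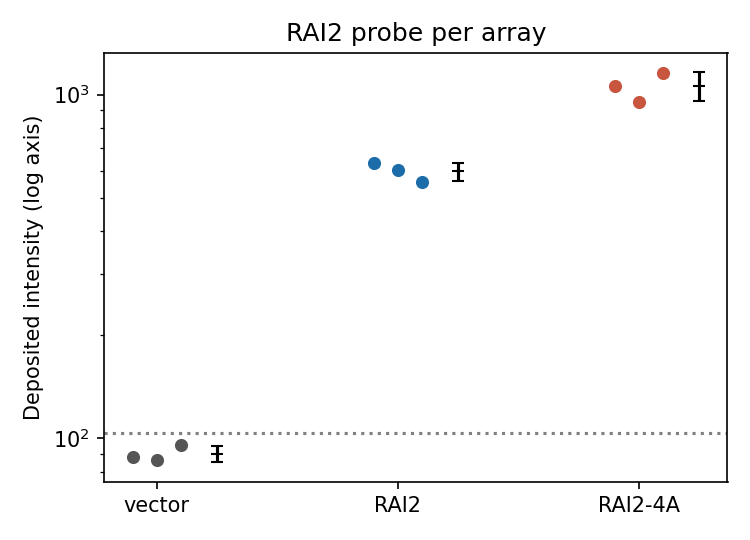
Deposited intensity of the RAI2 probe on a log axis for each of the 9 arrays (points), with the mean and SD of each group (n = 3, bar and whiskers); the dotted line is the highest background threshold of any array, an intensity of 104. All 3 vector arrays sit under the line, while the lowest of the other arrays reads 559.

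In RAI2 cells 40 genes were higher than in vector, RAI2 itself among them, and 12 were lower. With the main axis of the residuals as a covariate 108 were higher and 75 lower. That axis comes from the residuals of the same fit, so it lowers their spread by construction, and the larger count is no separate evidence. The beta-defensin DEFB103A, an antimicrobial peptide, rose by 2.86 log2 units (SE 0.16, limma, adjusted p = 8.33e-07), and it was above background in vector cells too. LRIG1, a negative regulator of ERBB receptors, rose by 1.36 (SE 0.17, limma, adjusted p = 0.0146 with every probe tested on its own) on a probe above background on 2 of 3 vector arrays. Its brightest probe, which stood for it in the counts (limma, adjusted p = 3.00e-05), was above background on 0 vector arrays, so its fitted difference of 1.95 was taken against background. The immunoglobulin superfamily member IGSF3, not above background in any vector array, rose at least 2.32-fold (limma, adjusted p = 7.57e-05). Falls included those of the teneurin TENM3, which fell by 1.05 log2 units (SE 0.10), the small GTPase RASD1, which fell by 1.02 (SE 0.11), and adrenomedullin (ADM), a vasoactive peptide, which fell by 0.96 (SE 0.13).

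In all, 52 of the 12420 genes passed an adjusted p of 0.05 in limma, 40 of them higher in RAI2 cells. A change of 2-fold or more was seen for 14 of the higher and 2 of the lower genes. The 3 RAI2 arrays did not overlap the 3 vector arrays for 10.1% of tested genes, where chance gives 10%. An unadjusted p under 0.05 was seen for 735 genes, a share slightly over the 0.05 that unchanged genes would give. Among the rises, APCDD1L increased by 1.41 log2 units, the matrix protein TGFBI by 1.36, the actin-bundling protein LCP1 by 1.35, the hyaluronan-binding protein CEMIP by 1.30 and the endothelial lipase LIPG by 1.15. LCP1 was above background in 2 of the 3 vector arrays. The monocyte chemoattractant CCL2 rose at least 2.03-fold from a level not above background in vector. Among the falls, RAB17 decreased by 0.85, the complement regulator subunit C4BPB by 0.80, the cancer-testis gene MAGEA12 by 0.80, FAM133A by 0.76, and the pregnancy-specific glycoproteins PSG4 and PSG6 by 0.75 and 0.71. TMEM163 was at least 1.48-fold lower, and was not above background in any RAI2 array. DEFB103A has a near-identical copy, DEFB103B, and PSG4 and PSG6 belong to a family of close paralogs, so the arrays may not separate these copies. Other probes of some of these genes differed less. They gave -0.05 for MAGEA12 (above background on 3 of 9 arrays), 0.48 for LIPG (8 arrays), 0.27 for IGSF3 (1 array) and -0.25 for PSG6 (9 arrays). For PSG4 they gave -0.03 (4 arrays) and -0.47 (9 arrays).

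The calls of RAI2, DEFB103A, LRIG1, IGSF3, APCDD1L, TGFBI, LCP1, CCL2, TENM3, RASD1 and ADM passed the threshold whichever single array was left out. Others were lost without single arrays of vector or RAI2: LIPG (highest adjusted p in limma 0.0516, RAI2 replicates 1 and 2), CEMIP (0.0968, vector replicate 3 and RAI2 replicates 1 and 2), MAGEA12 (0.0839, vector replicate 3 and RAI2 replicates 1 and 3), and PSG6 (0.111, vector replicate 3 and each RAI2 replicate). The same held for PSG4 (0.180, vector replicates 2 and 3 and RAI2 replicates 2 and 3), C4BPB (0.145) and TMEM163 (0.253), the latter pair without vector replicate 2 or 3 or any RAI2 replicate. FAM133A (0.161) was lost without the same 5 arrays or RAI2-4A replicate 3, and RAB17 (0.232) without any vector or RAI2 array or RAI2-4A replicate 1. Other settings ended calls too, with highest adjusted p values in limma for RAB17 (0.166), FAM133A (0.105) and TMEM163 (0.128) with every probe tested on its own, and for CEMIP (0.0789) with the background at the mode. They were highest with the mean of a gene's probes for LIPG (0.0662), C4BPB (0.125), MAGEA12 (0.354), PSG4 (0.308) and PSG6 (0.234), with differences of -0.42 for both MAGEA12 and PSG4. With the background at the mode the differences grew to 3.26 for LRIG1, 2.58 for IGSF3, 2.18 for LCP1, 2.20 for CCL2, 1.84 for LIPG, -1.41 for MAGEA12 and -1.48 for TMEM163. Those of LRIG1, IGSF3, CCL2 and TMEM163 are fitted differences from background and not measured folds. The count fell to 27 without vector replicate 3, to 21 without RAI2 replicate 1, to 21 without RAI2 replicate 2 and to 26 without RAI2 replicate 3. Without the 3 arrays that stood apart it was 58, of which 44 were among the 52.

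**Figure D2:**
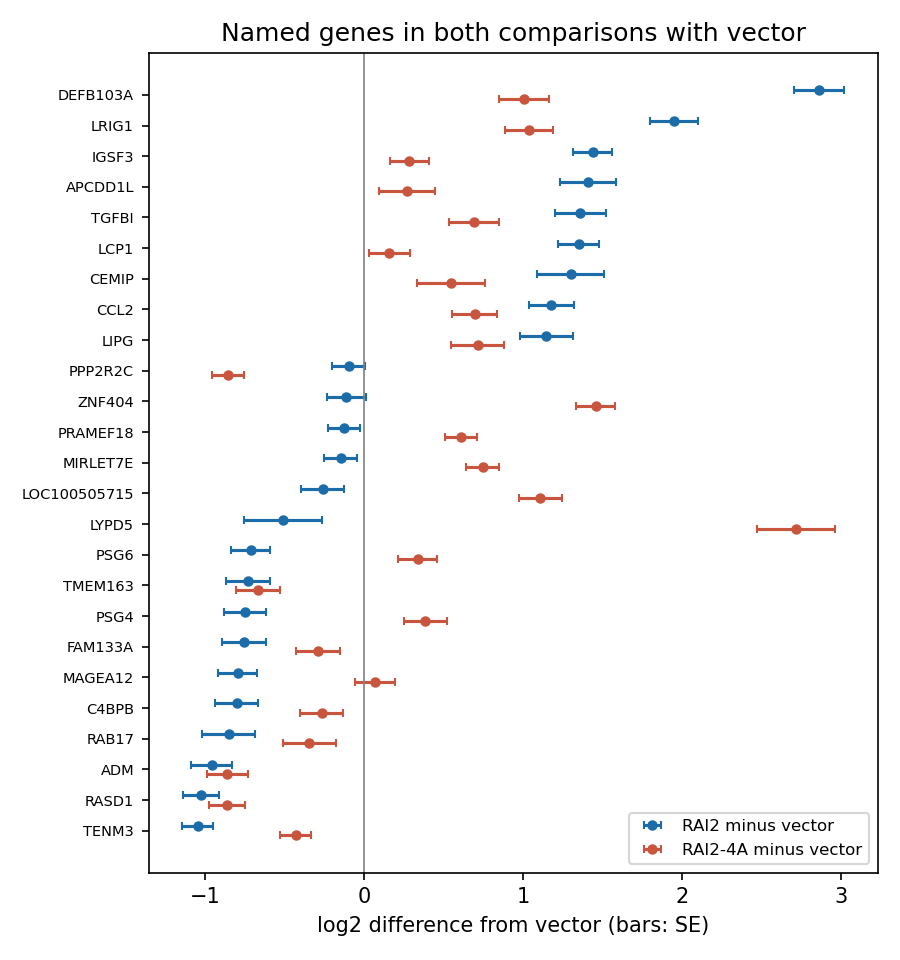
Log2 difference from vector, with its SE, for the genes named in the comparisons of RAI2 (blue) and RAI2-4A (red) with vector, RAI2 itself left out; each point rests on 3 against 3 arrays. Points of LRIG1, IGSF3, CCL2, TMEM163, MIRLET7E and PRAMEF18, whose plotted probes were not above background on any array of vector or of RAI2, are fitted differences from background and not measured folds. For MIRLET7E and PRAMEF18 the blue points set background against background. DEFB103A differs by 2.86 in RAI2 and 1.01 in RAI2-4A, while LYPD5 differs by -0.51 in RAI2 and 2.72 in RAI2-4A.

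Of the 39 gene lists fixed beforehand, 8 were higher in RAI2 than in vector relative to other genes by camera with its preset correlation, and few of their members passed the gene-level test. In the NF-kB and inflammatory list, 1 of 28 measured members rose (CCL2), none fell and 27 did not pass (camera, adjusted p = 8.10e-07, but adjusted p = 0.467 with an estimated correlation). Adjusted over the list alone, 5 rose: CCL2, CD83, IL32, PTGS2 and SAA1. The acute-phase gene SAA1 differed by 1.04 (SE 0.22) and CD83 by 0.54 (SE 0.11), neither past the threshold over all genes. In the interferon list, 1 of 39 members rose, the antiviral GTPase MX1, by 1.04 log2 units (SE 0.20, limma, adjusted p = 0.0406), and 38 did not pass (camera, adjusted p = 4.66e-05, but adjusted p = 0.499 with an estimated correlation). Adjusted over the list alone it was again 1. The call of MX1 was lost without vector replicate 1 or 3 or any RAI2 replicate, with a highest adjusted p in limma of 0.208, and it was 0.156 with the background at the mode.

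The other lists called were retinoic acid response (camera, adjusted p = 0.00779), CtBP target genes (0.0175), MHC class I presentation (0.0175), stemness (0.0246), leukocyte markers (0.0246) and mesenchymal genes (0.0463). None was called with an estimated correlation, where the lowest adjusted p of any list was 0.467. The calls of the NF-kB, interferon and retinoic acid lists passed whichever array was left out. Those of the CtBP target (highest adjusted p in camera 0.154) and mesenchymal (0.239) lists were lost without vector replicate 2 or 3 or RAI2 replicate 1 or 2, those of the MHC class I (0.294) and leukocyte (0.276) lists without vector replicate 2 or 3 or RAI2 replicate 2, and that of the stemness list (0.145) without vector replicate 1 or 2 or RAI2 replicate 1 or 2. Without the 3 arrays that stood apart the stemness (adjusted p in camera 0.0969) and leukocyte (0.0600) calls were lost and matrix proteases were called (0.00549), a list with an adjusted p = 0.499 with an estimated correlation over all arrays. With no filter on dim probes the leukocyte (0.127) and mesenchymal (0.373) calls were lost, with the background at the mode the mesenchymal (0.136) and stemness (0.0624) calls, with the residual axis as covariate the mesenchymal and leukocyte calls (both 0.0506), and with arrays scaled to 1 median the mesenchymal call (0.0542). Of 17 CtBP target genes none passed over all genes, and adjusted over the list alone 5 rose (BIK, CDKN1A, CDKN1C, IGFBP3 and PMAIP1, of which PMAIP1 and BIK are pro-apoptotic BCL2 family members); the cell cycle inhibitor CDKN1A differed by 0.48 (SE 0.12). Of 12 retinoic acid response genes none passed, and adjusted over the list alone 2 rose, PLAAT4 and the transglutaminase TGM2, which differed by 0.75 (SE 0.15). Of 17 mesenchymal genes none passed, and adjusted over the list alone 5 rose (CDH11, COL5A1, COL6A1, SNAI2 and TNC) while N-cadherin (CDH2) fell. Of 17 MHC class I genes none passed and adjusted over the list alone HLA-B rose. Of 14 stemness genes none passed on either basis. Of 10 leukocyte markers 1 rose, the lipopolysaccharide coreceptor CD14, by 0.88 (SE 0.14, limma, adjusted p = 0.0103) and by 0.46 on its other probe (4 arrays above background), and adjusted over the list alone HLA-DRA rose too. Outside the called lists, thrombospondin 1 (THBS1), of the integrin and matrix list, rose by 0.86 (SE 0.14), TGFBI, of the TGF-beta list, rose, and ADM, of the hypoxia list, fell. The call of CD14 was lost without vector replicate 3, RAI2 replicate 1 or RAI2 replicate 2 (highest adjusted p in limma 0.0789), and that of THBS1 without vector replicate 2, RAI2 replicate 1 or RAI2 replicate 2 (0.0831). The mean of a gene's probes ended that of CD14 (0.0662), and the background at the mode that of THBS1 (0.0795).

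The remaining 31 lists were not called: CtBP corepressor complex, luminal and estrogen receptor, basal breast, epithelial junction, bone and lung metastasis, TGF-beta response, YAP and TEAD targets, ERK feedback and output, immediate early, AKT and FOXO targets, p53 targets, apoptosis and the BCL2 family, G1/S and DNA replication, G2/M and mitosis, cholesterol synthesis, fatty acid synthesis, unfolded protein response, integrated stress response, heat shock, NRF2 response, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis and MYC, histones, integrins and matrix, matrix proteases, Notch and WNT targets, packaging cell markers, fibroblast and endothelial markers, and housekeeping. E-cadherin (CDH1), counted among CtBP targets, differed by 0.00 (SE 0.12).

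Between RAI2-4A and vector cells 11 genes differed, and those higher in RAI2-4A included 3 neighbouring genes. LYPD5, a GPI-anchored surface protein of the LY6/PLAUR family, rose by 2.72 log2 units (SE 0.25, limma, adjusted p = 0.000204), the zinc finger gene ZNF404 by 1.46 (SE 0.12, limma, adjusted p = 0.000130) and the uncharacterised LOC100505715 by 1.11 (SE 0.14, limma, adjusted p = 0.00462). DEFB103A rose by 1.01 log2 units (SE 0.16). LRIG1 passed on its brightest probe (limma, adjusted p = 0.0160), whose fitted difference of 1.04 was taken against background, as the probe was above it on 0 vector arrays. Its other probe, above background on 2 of 3 vector arrays, differed by 0.58 (SE 0.17) and did not pass (limma, adjusted p = 0.992 with every probe tested on its own). RASD1 fell by 0.86 (SE 0.11), ADM by 0.86 (SE 0.13) and the phosphatase subunit gene PPP2R2C by 0.86 (SE 0.10).

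The threshold was passed by 11 genes, 8 higher (RAI2 itself among them) and 3 lower. The residual axis as covariate, which lowers the residual spread by construction, gave 24 higher and 28 lower. The 2 not yet named, MIRLET7E and PRAMEF18, were at least 1.52-fold and at least 1.32-fold higher. Arrays of the 2 groups did not overlap for 8.0% of genes, where chance gives 10%. An unadjusted p under 0.05 was seen for 496 genes, a smaller share than the 0.05 that unchanged genes would give. Of 4 LYPD5 probes, 2 were above background on all RAI2-4A arrays, and both rose, by 2.72 and 2.82. The remaining LYPD5 probes, above background on 0 and 2 of 9 arrays, differed by 0.12 and 0.13. The calls of RAI2, LYPD5, ZNF404, LOC100505715 and PPP2R2C passed whichever array was left out, while RASD1 was lost without vector replicate 3 (adjusted p in limma 0.0546). LRIG1 (highest adjusted p 0.112) was lost without vector replicate 3 or RAI2-4A replicate 1 or 3, ADM (0.146) without these or vector replicate 2, and MIRLET7E (0.112) without vector replicate 2 or 3 or RAI2-4A replicate 1 or 2. DEFB103A (0.215) was lost without any vector array, RAI2 replicate 1 or RAI2-4A replicate 1 or 2, and PRAMEF18 (0.267) without any of the 9 arrays. Other settings ended calls too, with highest values for LRIG1 with the mean of a gene's probes (adjusted p in limma 0.132), DEFB103A (0.181) and ADM (0.0889) with every probe tested on its own, and MIRLET7E (0.0674) and PRAMEF18 (0.171) with only the groups compared in the fit. With the background at the mode the differences grew to 2.02 for LRIG1, 1.56 for MIRLET7E, 1.28 for PRAMEF18 and -1.60 for PPP2R2C. Those of LRIG1, MIRLET7E and PRAMEF18 are fitted differences from background and not measured folds. The count fell to 7 without vector replicate 2, to 5 without vector replicate 3 and to 6 without RAI2-4A replicate 1, and was 17 without the 3 arrays that stood apart, with 8 of the 11 among them.

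**Figure D3:**
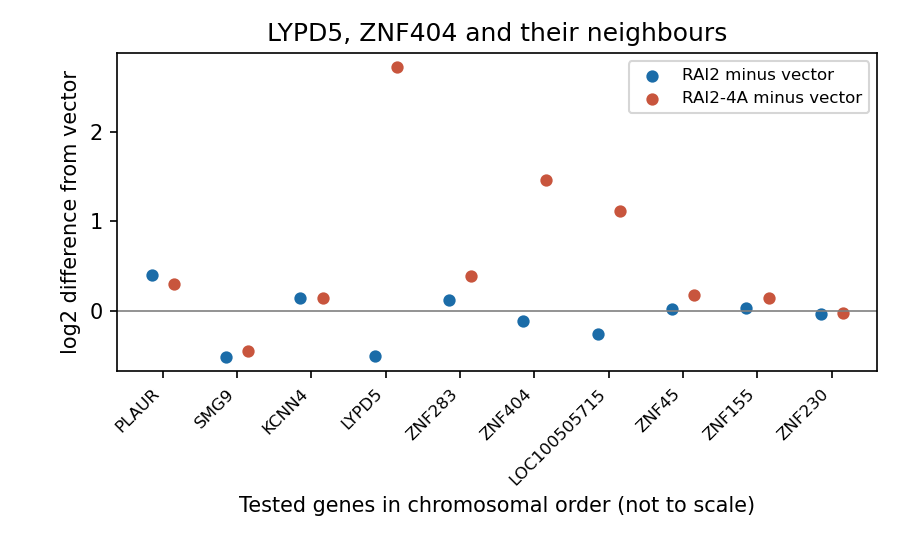
Log2 difference from vector of RAI2 (blue) and RAI2-4A (red), each 3 against 3 arrays, for LYPD5, ZNF404, LOC100505715 and tested genes beside them in chromosomal order, spaced evenly. In RAI2-4A the 3 genes differ by 2.72, 1.46 and 1.11, while ZNF283, which lies between them, differs by 0.38.

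For RAI2-4A, 3 lists were called against vector: NF-kB and inflammatory genes were higher (camera, adjusted p = 0.0231), leukocyte markers were higher (0.0375) and NRF2 response genes were lower (0.0423). With an estimated correlation their adjusted p values were 0.863, 0.342 and 0.342. All 3 calls were lost without vector replicate 2 or 3; the NF-kB call was also lost without RAI2-4A replicate 1 (highest adjusted p in camera 0.240), the leukocyte call without RAI2-4A replicate 3 (0.351) and the NRF2 call without vector replicate 1 or RAI2-4A replicate 1 or 2 (0.165). Without the 3 arrays that stood apart the NRF2 call was lost (adjusted p in camera 0.110) and MHC class I genes were called (0.00850), a list with an adjusted p = 0.970 with an estimated correlation over all arrays. With no filter on dim probes the leukocyte call was lost (0.239), and with the background at the mode the NRF2 call (0.115). No member of these lists passed over all genes. Adjusted over the list alone, CCL2 rose among 28 NF-kB genes, HLA-DRA among 10 leukocyte markers, and AKR1C2 fell among 18 NRF2 genes. The other 36 lists were not called. They included the interferon list (camera, adjusted p = 0.859) and the CtBP target genes (0.980). The interferon list leaned down over all arrays and up without the 3 arrays that stood apart (adjusted p in camera 0.0810), not called either way.

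Both comparisons use the same vector arrays. In the same direction, 5 genes were called in both: RAI2, DEFB103A and LRIG1 (on its brightest probe) higher, RASD1 and ADM lower. RAI2 is among them by design, as it was overexpressed in both groups. The number was 3 without vector replicate 2 and 1, RAI2 alone, without vector replicate 3. It was 2 without RAI2-4A replicate 1, 3 without RAI2-4A replicate 3, and 8 without the 3 arrays that stood apart. Independent lists would share 0.0258 higher and 0.00290 lower genes, and unchanged groups simulated against shared controls shared 0.11 on average. No gene differed in that simulation, so hardly any could be called, and its number of shared genes cannot judge the 5 seen. The number shared when RAI2 cells differ and RAI2-4A cells do not was not simulated. Fold changes correlated across genes with r = 0.57 (jackknife SE over arrays 0.256), where the simulation gave 0.501, and had a covariance of 0.0145, where it gave 0.00981 and the spread of the vector arrays alone gave 0.0182. Without the 3 arrays that stood apart r was 0.501, where the simulation gave 0.499, and the covariance was 0.0133, where it gave 0.00847. With same-numbered RAI2 and RAI2-4A arrays also correlated as their residuals were (0.371 on average), the simulation gave an r of 0.684, above the observed one. Its covariance was 0.0133, and its 0.06 shared genes have the same limit. Part of the overlap and of the correlation may come from the shared controls, which were too few to split, and from this pairing. Of the 51 genes other than RAI2 that were called in RAI2 cells, 40 (78.4%) had the same sign in RAI2-4A. The simulation gave 55.3% for called genes in an unchanged group, 57.8% with the pairing, and 66.7% over all genes of unchanged groups. The simulation took the observed differences of called genes as true and 1 spread per gene for all groups. That spread gave a lower covariance than the vector arrays alone, so the part of the shared controls may be understated. Of the 51 genes, 19 differed between RAI2 and RAI2-4A.

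Set directly against RAI2-4A, 24 genes were higher in RAI2 cells and 23 lower, RAI2 itself, LYPD5 and its neighbours among the latter. Because RAI2-4A cells also read higher on the RAI2 probe, the form and the level of RAI2 cannot be told apart in this comparison. DEFB103A was higher by 1.85 log2 units (SE 0.16, limma, adjusted p = 0.000118), the actin-binding gene AIF1L by 1.42 (SE 0.21), carbonic anhydrase CA2 by 1.24 (SE 0.14) and LCP1 by 1.19 (SE 0.13). LYPD5 was lower, with a difference of -3.22 (SE 0.25, limma, adjusted p = 5.31e-05), as were ZNF404 at -1.57 (SE 0.12) and LOC100505715 at -1.37 (SE 0.14). The activin antagonist follistatin (FST) was lower by a difference of -0.99 (SE 0.19).

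Here 47 genes passed. IGSF3, which was above background on 2 of the 3 RAI2-4A arrays, was higher by 1.15, APCDD1L by 1.14, MPZL2, on a probe above background on 1 of 3 RAI2-4A arrays, by 1.09, the interleukin 7 receptor IL7R by 1.04, cyclin D2 (CCND2) by 1.00 and the potassium channel KCNK1 by 1.00. Among the lower genes, AADACP1 differed by -1.22 and its neighbour and paralog AADAC, above background on 2 of 3 RAI2 arrays, by -0.98, PSG4 by -1.13, PSG6 by -1.05, PAGE5 by -0.98 and CTAGE1 by -0.96. Probes disagreed for MPZL2, whose other probe above background on 8 arrays differed by 0.03, and for CTAGE1, whose other probe (3 arrays) differed by 0.20. Other probes gave -0.06 for IGSF3 (1 array), -0.13 (4 arrays) and -0.55 (9 arrays) for PSG4, -0.59 for PSG6 (9 arrays) and 0.55 for CCND2 (9 arrays). Groups did not overlap for 11.3% of genes, where chance gives 10%. An unadjusted p under 0.05 was seen for 601 genes, a smaller share than the 0.05 that unchanged genes would give. The call of APCDD1L was lost without RAI2 replicate 1 or 2 (highest adjusted p in limma 0.0639), that of CCND2 without RAI2 replicate 1 or 3 or RAI2-4A replicate 2 (0.0825), and that of PAGE5 without RAI2 replicate 3 or RAI2-4A replicate 1 or 2 (0.110). FST (0.242) was lost without vector replicate 2, RAI2 replicate 1 or 2 or any RAI2-4A replicate. With replicate number as a block its adjusted p in limma was 0.0431 over all groups and 0.0911 over RAI2 and RAI2-4A only. The mean of a gene's probes ended the calls of PSG4 (adjusted p in limma 0.0573, difference -0.61) and CTAGE1 (0.222, -0.38) and gave 0.56 for MPZL2. Other settings ended those of FST (0.188 with a trended, robust variance) and, with the background at the mode, APCDD1L (0.0619), CCND2 (0.0588) and PAGE5 (0.0657). With the background at the mode the differences grew to 1.84 for LCP1, 2.06 for IGSF3, 2.07 for MPZL2, 1.67 for KCNK1, -1.94 for AADACP1, -1.73 for AADAC and -1.52 for CTAGE1. The count was 77 without vector replicate 1, 30 without RAI2 replicate 1, 31 without RAI2 replicate 3 and 56 without the 3 arrays that stood apart, with 42 of the 47 among them.

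Of the 39 lists, 8 were higher in RAI2 than in RAI2-4A by camera: interferon response (adjusted p = 1.13e-06), matrix proteases (0.000490), CtBP target genes (0.0115), NF-kB and inflammatory (0.0115), integrins and matrix (0.0115), NRF2 response (0.0121), stemness (0.0121) and mesenchymal genes (0.0158). None was called with an estimated correlation, where the lowest adjusted p was 0.283 and that of the interferon list was 0.770. The calls of the interferon and matrix protease lists passed whichever single array was left out, but not without the 3 arrays that stood apart. Without RAI2-4A replicate 2 the NF-kB, integrin, NRF2, stemness and mesenchymal calls were lost, without RAI2 replicate 1 the CtBP target, NF-kB, stemness and mesenchymal calls, without RAI2 replicate 2 the integrin call and without RAI2-4A replicate 3 the NF-kB call, with highest adjusted p values in camera from 0.0532 for NRF2 to 0.407 for NF-kB. None of the 39 interferon genes passed over all genes. Adjusted over the list alone, 9 were higher (HERC6, IFI27, IFI44, IFIT1, IFIT3, ISG15, ISG20, MX1 and OASL), with differences of 0.78 (SE 0.19) for OASL and 0.52 (SE 0.12) for IFIT1. Of 22 matrix protease genes none passed, and adjusted over the list alone CTSL and SERPINE2 were higher. Of 17 CtBP target genes none passed, and adjusted over the list alone IGFBP3 was higher. The 1 mesenchymal gene past the threshold, CDH2, went against its list with a difference of -0.64 (SE 0.11), a call that was lost without RAI2 replicate 2 or 3 or any RAI2-4A replicate (highest adjusted p in limma 0.147). With replicate number as a block its adjusted p in limma was 0.0667 over all groups and 0.0403 over RAI2 and RAI2-4A only. Adjusted over the list alone COL6A1, TAGLN and TNC were higher. NF-kB, integrin and matrix, NRF2 and stemness genes had no member past the threshold on either basis. Without the 3 arrays that stood apart, 1 list was called in place of 8, NF-kB (adjusted p in camera 0.00851), and the interferon (0.0810) and matrix protease (0.0527) calls were among those lost. CDH2 then had an adjusted p in limma of 0.0804, and with the background at the mode its difference was -1.02. The other 31 lists were not called.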

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

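Only the tests on other splits of the arrays were planned, and all other tests in this part were chosen after the results were seen. Probes without a gene symbol were outside the comparisons. Among the 5983 kept, 4 were higher in RAI2 than in vector at an adjusted p under 0.05 in limma, 2 were lower, and 0 passed between RAI2-4A and vector. In RAI2 against vector ILMN_1660067 differed by 1.37 log2 units (limma, adjusted p = 0.00845). Between RAI2 and RAI2-4A 3 passed, 2 of them higher in RAI2.

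Of the 10 splits of the 6 arrays of each comparison into 3 and 3, 1 gave as many genes, the real one. The real values were 52 genes for RAI2 against vector, 11 for RAI2-4A against vector and 47 for RAI2 against RAI2-4A, and the highest other split gave 0 in each. With 10 splits a share under 0.05 cannot be reached. Replicate numbers may pair RAI2 with RAI2-4A. Of the 4 splits of these arrays that part all 3 pairs the other 3 gave 0 genes, as did the 6 that part 1 pair.

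Vector replicate 1, RAI2 replicate 2 and RAI2-4A replicate 2 shared a pattern that held 53.4% of the within-group variance. A RAI2 or RAI2-4A array labelled as vector is argued against, since the RAI2 probe on vector replicate 1 read 88.3, under its threshold of 100.3, against at least 559 in the other groups. A change in transcript level and a labelling or hybridisation difference acting probe by probe cannot be told apart, because only 16 of the 200 genes on the axis have another bright probe. The median ratio of the other probe to the first was 0.234 (95% interval -0.00929 to 1.04), and 62.5% of the other probes lay under 50% of the first (95% interval 35.4% to 84.8%). No biological explanation that the design names was tested for it.

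LYPD5, ZNF404 and LOC100505715, neighbours with 1 tested gene between them, were higher in RAI2-4A. Cross-hybridisation of a single LYPD5 probe is argued against by another probe, which rose by 2.82 (SE 0.19). That probe was taken for having the largest difference among the other probes, and the rest, near background, differed by 0.12 and 0.13. A gain of a wide segment is argued against by the 20 flanking genes, whose median difference was 0.00 log2 units (0.00186, 95% interval -0.0893 to 0.144). A change shared along a stretch of chromosome stays open, since ZNF283 between them differed by 0.38 (95% interval 0.113 to 0.653), which spans 50% of the smallest of the 3 differences (0.55). A retroviral insertion near these genes, carried by many of the cells, may be a candidate cause, as a hypothesis not tested here. Action of RAI2-4A itself also stays open, as untested.

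The NF-kB and interferon lists were higher in RAI2 than in vector by camera with its preset correlation, but not with an estimated one. The 3 arrays that stood apart are argued against as the source of these calls at the preset correlation, the only one run without them. Without them the NF-kB list had an adjusted camera p of 1.68e-12, within a range over alternatives of 1.68e-12 to 0.467. That of the interferon list was 4.34e-05, within a range of 1.80e-06 to 0.499. Leukocyte RNA stays open, since the leukocyte list was itself higher (camera, adjusted p = 0.0246, but adjusted p = 0.467 with an estimated correlation and 0.0600 without the 3 arrays) in 8 of 10 members, CD14 rose by 0.88, and of 6 abundant leukocyte genes 1 (LAPTM5, also above in vector) was above background on all RAI2 arrays, the others lying too near background to decide. Movement of co-regulated genes from culture to culture stays open. With an estimated correlation the adjusted camera p was 0.467 for the NF-kB list and 0.499 for the interferon list. An effect of RAI2 on these genes also stays open, as a hypothesis.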

How the results depend on the processing

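The alternatives that left out the 3 arrays together, used the residual axis as covariate, set the background at the mode, blocked replicate number in RAI2 and RAI2-4A only or applied quantile normalization after background correction were chosen after the data were seen. Of 28 alternatives, 9 left out 1 array each. Of the called genes and lists, 0 changed direction in any alternative that measured them. Sizes did move: of 54 named calls, 19 differences grew by over 1.5 times with the background at the mode, and 5 shrank as much with the mean of a gene's probes. Named calls ended were 13 with the background at the mode, 15 with the mean of a gene's probes and 19 with every probe tested on its own. Where a count moved by over 1.5 times the cause was not tested, except that fewer genes (9551) were tested with the stricter filter.

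With the stricter filter on dim probes 6 genes passed in RAI2-4A against vector, 25 in RAI2 against RAI2-4A and 3 in both comparisons with vector, and 5 lists were called for RAI2-4A. With the mean of a gene's probes 33 passed in RAI2 against vector. In RAI2-4A against vector 7 passed with every probe tested on its own, 7 with only the groups compared in the fit and 17 with a trended, robust variance. Array weights gave 88, 25 and 79 genes for RAI2 against vector, RAI2-4A against vector and RAI2 against RAI2-4A. With an estimated correlation 0, 0 and 0 lists were called in these comparisons, and with fry 0, 0 and 0. The background at the mode left 3 genes called in both. Without the 3 arrays 17 genes passed for RAI2-4A, 8 in both, and 1 list was called in RAI2 against RAI2-4A. The residual axis as covariate, which lowers the residual spread by construction, gave 183 (108 higher), 52 (24 higher) and 107 (65 higher) genes. With it 22 genes were called in both, and 5 lists for RAI2-4A.

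Leaving out 1 array at a time gave 21 to 56, 5 to 11 and 30 to 77 genes, 3 to 10, 0 to 4 and 3 to 9 lists, 1 to 5 genes in both, and a correlation of 0.460 to 0.727. The log2 differences of RAI2 itself were then 3.05 to 3.16 and 3.87 to 4.02. They are fitted differences from background in vector and not measured folds. With replicate number as a block 38, 9 and 38 genes passed, and 47 in RAI2 against RAI2-4A with the block in those groups only. In that comparison the blocks ended no named call but CDH2 or FST and no list call. The numbers did not pair vector with the others, and 2 of 9 arrays correlated best with their own number. Normexp on raw values and the slide as a block were not run. Signal over background limits dim genes to bounds on their fold.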

Other observations

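The genes in this part were chosen after their values were seen, and no further tests were run on them. None but RAI2 passed the threshold over all genes in these comparisons. The list of luminal and estrogen receptor genes, which holds RAI2, was not called in RAI2 against vector (camera, adjusted p = 0.605). Its median log2 difference was -0.12 and its mean, raised by RAI2, was 0.10. Adjusted over the list alone, 2 of its 14 measured members fell, the luminal transcription factor SPDEF with a difference of -0.72 (SE 0.15, limma, adjusted p over all genes = 0.0715) and the secretory protein AGR2 with -0.46 (SE 0.14, 0.420). In RAI2-4A against vector AGR2 differed by -0.75 (SE 0.14) and passed adjusted over the list alone, while SPDEF differed by -0.33 (SE 0.15) and did not.

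Among 22 matrix protease genes, not called in RAI2 against vector (camera, adjusted p = 0.116) but called without the 3 arrays that stood apart (0.00549; adjusted p = 0.499 with an estimated correlation over all arrays), 4 rose adjusted over the list alone: CTSL, the plasminogen activator PLAT, the urokinase receptor PLAUR and the protease inhibitor SERPINE2. PLAT differed by 0.53 (SE 0.14) and PLAUR by 0.40 (SE 0.11). Among 19 bone and lung metastasis genes KYNU and TNC rose adjusted over the list alone, with differences of 0.54 (SE 0.13) and 0.77 (SE 0.17).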
